A study of Homo sapiens with 16 samples.

How the data were processed

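The samples were 16 libraries of reduced representation bisulfite sequencing from the human embryonic stem cell lines HES-1 and HES-2, with 3 conventional, 3 LN and 2 naive libraries of each line. Per the labels' protocols, cells were detached with collagenase, genomic DNA was extracted and the libraries were converted with a commercial bisulfite kit. The submitters' processing notes name FastQC, Trim Galore, Bismark and the GRCh38 assembly, without versions or the role of each tool. Bisulfite converts unmethylated cytosine, and the share of cytosines that remain is read as methylation. Incomplete conversion would raise levels, and a tile covered by few reads would take coarse values.

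The authors deposited a single table for the series, whose values are percent methylation from 0 to 100 in each library, per the file headers and the values themselves. It holds 63704 tiles of 100 bp, each with a start and an end, and no missing values. How CpGs were combined into a tile and which tiles were kept is not given in the sources used here. The table gives no coverage, so the depth per sample and per tile is unknown, no interval could be computed, no coverage minimum was applied, and tests could not use methylated and unmethylated read counts. All 16 sample columns were used, and 0 measurement columns were left out. The 175 tiles outside the autosomes and chromosome X stayed in the analysis of all tiles and entered no chromosome comparison.

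Tiles were linked to genes with the RefSeq annotation of GRCh38.p14, the same assembly as the table. The plan was to use tiles within 1000 bp upstream and 500 bp downstream of a transcription start. The gene table used here gives no strand, so tiles that overlap a window from 1000 bp outside to 500 bp inside either end of a gene were used instead, which mixes starts and 3' ends. Exons, introns and UTRs were not used here. Of 43392 named genes, 13422 had at least 1 tile in such a window, with a median of 2 tiles per gene, and 10394 of them code for proteins. The windows held 27121 tiles (42.6%), a further 26344 lay elsewhere within genes and 10239 in neither. A gene's level is the mean of its tiles.

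Tests were fitted with limma 3.58.1 in R 4.3.3 on percent levels, with 6 group means (line by condition), empirical Bayes moderation with a trend on the mean level, and Benjamini-Hochberg adjustment over all tiles or all genes. A call needed an adjusted p below 0.05 and a difference of at least 20 percentage points. Differences between conditions are the average of the differences in both lines. Library means, shares of tiles below 20% and above 80%, and the mean of chromosome X minus that of autosomes were tested with two-sided exact permutation tests within line, computed with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15. Called tiles within 1000 bp of each other were also merged into regions.

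There were 14 gene lists, fixed before the data were examined together with the tests and the alternatives: naive pluripotency, post-implantation and primed epiblast, core pluripotency, imprinted genes, germline and cancer-testis genes, HOX clusters, germ layer regulators, trophoblast and extraembryonic genes, protocadherin clusters, zinc finger genes, the DNA methylation machinery, genes recurrently aberrant in cultured pluripotent cells, fibroblast genes and neural genes. The zinc finger list takes every symbol that starts with ZNF and a digit, antisense genes included. Lists were tested with camera at a preset correlation of 0.01, against all other genes, and again with an estimated correlation. Named genes follow a rule set at the same time: for each comparison of conditions, the 8 tiles with a gene name and the largest difference in each direction that were called, with the same sign in both lines and libraries that did not overlap in either, up to 2 called members of each list with the largest difference, and 10 fixed pluripotency genes. Of the fixed genes, TFCP2L1 and ZFP42 had tiles and the other 8 did not. Genes outside the rule are named as chosen after their values were seen.

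The fit was tested on simulated data of 63704 tiles, with 200 tiles changed. For naive against conventional cells, 62 of 67 changes of 25 points (92.5%) and 66 of 66 of 40 points were called, 2 of 67 of 15 points, which lie under the required size, and 0 of 63504 unchanged tiles. For LN against conventional cells the counts were 66 of 67 (98.5%), 66 of 66, 2 of 67 and 1 of 63504.

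The alternatives were a term for the replicate number, a logit scale with levels kept within 1 and 99%, a minimum difference of 10 points or none, leaving out tiles below 5% or above 95% in all libraries, centring each library on its median, library weights, leaving out each library in turn, an additive model, autosomes only, medians in place of means, and class limits of 10 and 90%. Robust moderation, fits without the naive or without the LN libraries, the merging of tiles into regions, autosomes only for the comparisons of lines, distinct tiles for protocadherins and Fisher's exact test on lists were added after seeing the data, as were permutation tests of line by culture in which the line difference was removed first. Figures were drawn with matplotlib 3.10.9.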

Results

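DNA methylation was measured by reduced representation bisulfite sequencing, which reads the CpG-rich part of the genome, in 2 human embryonic stem cell lines, HES-1 and HES-2. Each line was grown in 3 ways. Conventional (primed) cells grew on mouse fibroblast feeder cells in serum replacement medium with FGF2. LN cells grew on mouse laminin-111 in a defined medium with FGF2, without feeder cells. Naive cells were kept in the 5iLFA medium, a mix of kinase inhibitors and growth factors that holds cells in a state resembling the epiblast before implantation. There were 3 conventional, 3 LN and 2 naive libraries of each line, 16 in all. The table held the methylation level, in percent, of 63704 tiles of 100 bp on the human GRCh38 assembly, with a value in every library. Of these, 61811 lay on autosomes and 1718 on chromosome X. The depth behind each value is unknown, because the table gives levels and no read counts, so no interval is given for a single level. The labels do not say whether replicates were separate cultures, and the p-values below measure the spread between these libraries. Values are mean ± SD over the libraries of a group, differences are given in percentage points with the standard error (SE) of the fit, and a tile or gene is called higher or lower only at a limma adjusted p below 0.05 and a difference of at least 20 points.

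Comparing the 3 culture conditions asks how far the level of methylation itself differs between states of pluripotency. Naive cells were far less methylated than both other cultures: their mean level was 14.7% ± 0.42 in HES-1 (n = 2) and 14.5% ± 0.05 in HES-2 (n = 2). Conventional cells stood at 32.6% ± 0.03 in HES-1 (n = 3) and 34.8% ± 0.15 in HES-2 (n = 3). LN cells lay slightly above them, at 33.4% ± 0.29 in HES-1 (n = 3) and 36.0% ± 0.17 in HES-2 (n = 3). Averaged over both lines, naive minus conventional was -19.07 points (-17.87 in HES-1 and -20.27 in HES-2), LN minus conventional 1.0 (0.85 and 1.15) and LN minus naive 20.07 (18.72 and 21.42). In a two-sided exact permutation test within line the p-values were 0.01, 0.005 and 0.01, each the smallest the design allows, and all 3 were 0.01 after Benjamini-Hochberg adjustment. Within a single line no exact p can go below 0.1; there the libraries of the conditions did not overlap in any of the 6 comparisons.

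The loss in naive cells was carried by highly methylated tiles, which moved to intermediate levels. Tiles above 80% made up 31.49% of all tiles in conventional and 32.33% in LN cells, but 0.19% in naive cells. Tiles between 20 and 80% rose from 6.62% in conventional to 28.11% in naive cells, and those below 20% from 61.89 to 71.71% (exact permutation p = 0.01 for each share, the smallest possible). Between LN and conventional cells the shares below 20%, between and above 80% differed by -1.57, 0.73 and 0.84 points (exact permutation p = 0.005 each). With limits of 10 and 90% the share of the highest class was lower in LN cells, by -0.6 points (exact permutation p = 0.66).

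**Figure D1:**
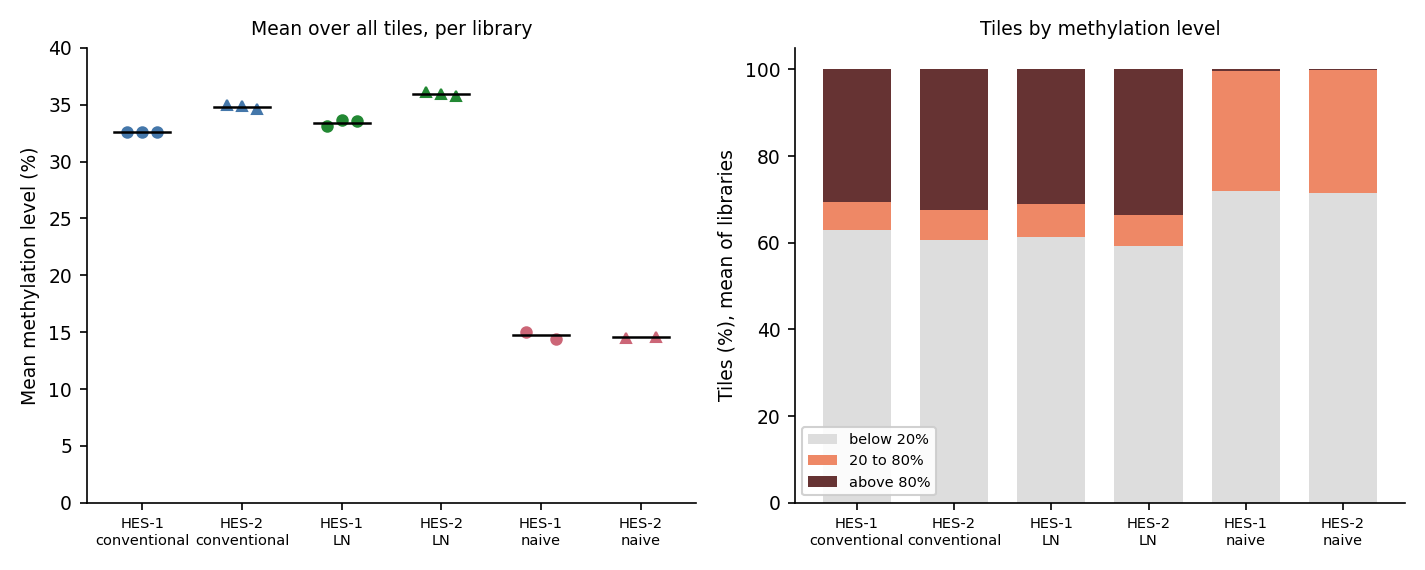
Left, the mean methylation level (%) of each library over all tiles, by cell line and culture condition, with a line at the group mean; right, the share of tiles (%) below 20%, from 20 to 80% and above 80%, as the mean of each group's libraries. Naive libraries lie near 14.6% against 33.7% in conventional and 34.7% in LN libraries, and hardly any of their tiles exceed 80%.

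The comparison of naive with conventional cells asks which genes and regions take part in this loss. Most measured germline genes (15 of 22) and clustered protocadherins (16 of 22) and 12 of 30 imprinted genes were lower in naive cells, some of them by nearly the full range, while 4 of 31 HOX genes and 2 of 36 germ layer regulators were higher. DPPA5, a gene active in early embryonic and naive cells, fell from 94.2% ± 0.9 to 0.0% ± 0.0 in HES-1 and from 96.8% ± 0.7 to 0.1% ± 0.1 in HES-2 (difference -95.5 ± 1.0 SE, adjusted p = 1.2e-15). BARX1, a homeobox gene of craniofacial and stomach development, rose at the tile at chromosome 9, 93952101 to 93952200, from 2.6% ± 0.8 to 77.7% ± 8.9 in HES-1 and from 2.1% ± 2.2 to 72.0% ± 15.1 in HES-2. Across the genome 23191 tiles were lower and 632 higher in naive cells, 37.4% of all tiles, and merging tiles within 1000 bp left 18462 lower and 417 higher regions.

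The tiles that fell had a mean level of 85.4% in HES-1 and 90% in HES-2 conventional cells and of 35.9 and 35.2% in the naive cells. Those that rose started at 5.3 and 7.6% and reached 41 and 42.2%. The changes of the lines overlapped: 21830 tiles were called lower in each line taken alone, where independent calls would share 8386, and 496 of the 666 higher in HES-1 and 643 higher in HES-2 were called higher in each, where 6.72 would be shared. A fall of 20 points needs a conventional level of at least 20%, and 63.06% of tiles in HES-1 and 60.72% in HES-2 lay below it. Of all tiles, 34.76 and 37.87% were called lower, so most tiles able to fall did so. The 8386, taken over all tiles, therefore understates the overlap that the starting level alone would give. Of the tiles higher in HES-1, 28 were called lower in HES-2. Of 13422 genes with a tile near either end, 1980 were lower and 51 higher, of which 1091 and 32 code for proteins.

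Among the genes that lost methylation, large changes at single tiles were found at TPTE, a phosphatase gene expressed in testis (chromosome 21, 10521301 to 10521400, -97.9 ± 0.7 SE). Others lay at the pseudogenes LONRF2P2 (-97.6 ± 0.7) and ETFRF1P1 (-97.5 ± 1.0), NAPSA, the gene of the aspartic protease napsin A (-97.3 ± 1.0), the testis-expressed retrogenes RPL10L (-97.2 ± 1.1) and RBMXL2 (-97.1 ± 1.6), and the pseudogene SAPCD2P4 (-97.0 ± 1.2). Pseudogenes share sequence with their parent genes, so reads may have been placed at either copy.

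Of 22 measured germline and cancer-testis genes, 15 were lower in naive cells and none higher. SYCP3, a component of the synaptonemal complex of meiosis, fell from 95% ± 2.1 to 0.0% ± 0.0 in HES-1 and from 97.4% ± 1.2 to 0.5% ± 0.7 in HES-2. The list moved down against all other genes (camera adjusted p = 6.1e-08, and 0.0024 with an estimated correlation). Its mean level in conventional cells was 63.4% in HES-1 and 66.5% in HES-2. A list that starts high has more to lose, and the test was not matched on starting level. It therefore cannot tell whether these genes lost more than others that started as high. Clustered protocadherins, cell adhesion genes of neurons that are arranged in 3 neighbouring arrays, were lower at 16 of 22 genes (camera adjusted p = 2.1e-08, and 0.0011 with an estimated correlation), among them PCDHGA7 (-95.2 ± 1.0 SE) and the antisense gene PCDHB1-AS1 (-94.4 ± 1.5). Some of these genes share an annotated end, and over the 33 distinct tiles behind the list the median difference was -55.6 points with 21 tiles lower. This list also started high, at 62.7% in HES-1 and 63.3% in HES-2 conventional cells. No list test in this comparison was matched on starting level.

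Imprinted genes, which are expressed from 1 parental copy, were lower at 12 of 30. MEG3, a non-coding RNA gene of the imprinted region on chromosome 14 (100826108 to 100861026), fell from 96.8% ± 0.7 to 1.0% ± 1.0 in HES-1 and from 95.5% ± 1.8 to 0.5% ± 0.1 in HES-2, and CMKLR2-AS differed by -96.2 ± 1.0 SE. In conventional cells CMKLR2-AS stood at 95.6% in HES-1 and 97.1% in HES-2. At such levels most copies were methylated, so the losses at MEG3 and CMKLR2-AS do not show the loss of a mark on 1 parental copy. Tiles were taken at gene ends, and regions that control imprinting were not examined. The list as a whole did not pass camera (adjusted p = 0.13), while Fisher's exact test of called members, added after the data were seen, gave an adjusted p of 0.0047 for lower genes. Genes reported as recurrently aberrant in cultured pluripotent cells were lower at 6 of 14, MEG3 again among them (camera adjusted p = 0.023, and 0.048 with an estimated correlation).

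Of 11 measured genes linked to naive pluripotency, 3 were lower (camera adjusted p = 0.24). Besides DPPA5 these were ALPP, the placental alkaline phosphatase gene (-61.0 ± 3.4 SE), and ZFP42, also known as REX1, a marker of undifferentiated cells, which fell from 34.4% ± 9.4 to 0.7% ± 0.1 in HES-1 and from 71.9% ± 6.2 to 1.8% ± 0.8 in HES-2 (-51.9 ± 3.3). TFCP2L1, a transcription factor of the naive state, was at 0.3% or less in all 6 groups (-0.2 ± 0.1, adjusted p = 0.19). Zinc finger genes, most of them of the KRAB type that silences transposable elements, were lower at 77 and higher at 2 of 386 (camera adjusted p = 0.026, and 0.0099 with an estimated correlation), led by ZNF534 (-94.6 ± 1.1) and the antisense gene ZNF350-AS1 (-93.8 ± 1.4). Genes of the methylation machinery were lower at 2 of 9, among them TRIM28 (-27.9 ± 1.0), the corepressor of KRAB proteins (camera adjusted p = 0.33).

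Fewer genes gained methylation in naive cells, among them 4 HOX genes and 2 germ layer regulators. The tile shared by HOXD3 and HOXD4 (chromosome 2, 176152901 to 176153000) rose from 4.3% ± 2.1 to 65.2% ± 0.8 in HES-1 and from 8.1% ± 4.4 to 66.5% ± 7.2 in HES-2. Over their end windows HOXD4 rose by 36.5 points (SE 1.9) and HOXD3 by 35.0 (SE 1.3). In the germ layer list 2 heart regulators rose, NKX2-5 by 30 (SE 2.4) and TBX5 by 29.6 (SE 3.0). IRX6, an Iroquois homeobox gene, rose by 56.3 points (SE 3.3) at chromosome 16, 55331101 to 55331200. Under the rule for named tiles, further large gains lay at the non-coding genes LINC01956 (62.0 ± 1.7 SE), LINC03010 (59.9 ± 2.7), MIR4740 (59.0 ± 2.0), LINC00682 (57.6 ± 1.6) and LINC01726 (52.0 ± 4.4). Some tiles outside that rule gained more than these, such as a tile of OSR2 (70.3 ± 2.1), chosen after its values were seen.

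Of 31 measured HOX genes, 4 were higher and none lower in naive cells, against 0.38% higher and 14.8% lower among all genes. The list median was -0.18 points, its mean 4.47, and camera placed it above other genes (adjusted p = 0.0021), which was lost with an estimated correlation (adjusted p = 0.069). Fisher's exact test of called members, added after the data were seen, gave an adjusted p of 5.0e-05 for higher HOX genes. HOXD3 and HOXD4, both among the higher genes, share a tile. The called genes are thus not independent, as that test takes them to be, and distinct tiles were not counted for this list. Germ layer regulators, higher at 2 and lower at 1 of 36, stood above other genes in both forms of the test (adjusted p = 3.4e-07 and 0.0024). The 14 genes of the post-implantation and primed epiblast had none called, with 9 at an unadjusted limma p under 0.05, and their median difference of 0.35 points lay above that of other genes (adjusted p = 5.1e-04 and 0.0083). In these relative tests "above" is measured against a background in which 14.8% of all genes fell. In conventional cells of HES-1 and HES-2 the mean level was 2.6 and 3% for the HOX list. It was 1.8 and 3.1% for the germ layer list and 0.2 and 2.9% for the post-implantation list. Genes at such levels could hardly fall, so a place above other genes does not by itself show a gain. For the post-implantation, fibroblast and neural lists the median was positive (0.35, 0.12 and 0.12) and the mean negative (-0.08, -7.1 and -4.28).

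The remaining lists did not pass the test against other genes. None of 6 core pluripotency genes (adjusted p = 0.48; 2 at an unadjusted p under 0.05) and none of 8 trophoblast and extraembryonic genes (adjusted p = 0.13; 6 at an unadjusted p under 0.05) was called. Among markers of other cell types, 2 of 8 fibroblast genes were lower, COL6A1 (-46.6 ± 1.3 SE) and COL6A3 (-29.4 ± 3.1; list adjusted p = 0.24), and 1 of 12 neural genes, GFAP (-55.8 ± 2.7; list adjusted p = 0.058). The neural list came to adjusted p-values from 0.037 to 0.050, above other genes, when HES-1 conventional replicate 1, HES-2 LN replicate 2, HES-2 conventional replicate 1 or 2, or HES-1 naive replicate 1 was left out. Counts adjusted over the list alone were the same for every list in this and the following comparisons. When each library was centred on its median, the calls for the post-implantation, HOX, germ layer and zinc finger lists were lost (adjusted p = 0.12, 0.57, 0.088 and 0.088), and without HES-1 naive replicate 1 the zinc finger list had an adjusted p of 0.062.

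**Figure D2:**
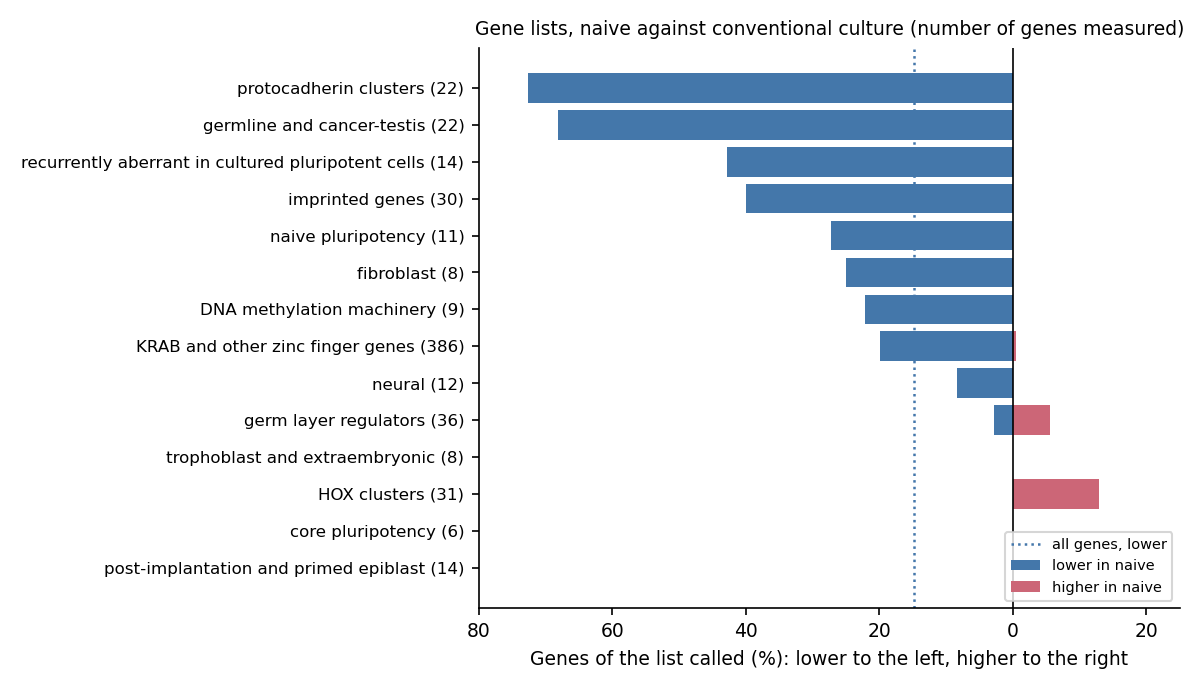
For each gene list, the percentage of its measured genes called lower (left of 0) or higher (right of 0) in naive than in conventional cells, with the number of genes measured in brackets and a dotted line at the 14.8% of all genes that were lower. Protocadherin and germline lists have the largest lower shares, and the HOX list the largest higher share.

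Comparing LN with conventional cells asks how the laminin-based culture, kept without feeder cells, differs from the primed state. The difference was small in extent and nearly all in the direction of gain: 861 tiles were higher and 17 lower in LN cells, 1.4% of all tiles. LEFTY1, which encodes an inhibitor of NODAL signalling, rose at chromosome 1, 225888801 to 225888900, from 25.5% ± 2.8 to 67.9% ± 5.0 in HES-1 and from 30.9% ± 4.3 to 89.2% ± 2.5 in HES-2 (50.3 ± 2.3 SE, adjusted p = 1.1e-06). UTF1, a chromatin-bound factor of undifferentiated cells, rose from 14.1% ± 3.2 to 44.4% ± 14.8 in HES-1 and from 23% ± 6.0 to 83.4% ± 4.9 in HES-2 (45.4 ± 4.5). IFITM1, an interferon-induced membrane protein gene, rose from 2.8% ± 0.3 to 21.7% ± 7.2 in HES-1 and from 5.1% ± 1.0 to 71.0% ± 13.6 in HES-2 (42.4 ± 4.0), a change that differed between the lines by -46.9 points (HES-1 minus HES-2, SE 8.0, adjusted p = 0.041).

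Under the rule for named tiles, other large gains lay at NNT-AS1 (49.9 ± 5.1 SE), at ABTB1 (45.0 ± 3.4), at the non-coding gene LINC00567 (43.4 ± 4.9), at MIR200BHG, the host gene of microRNAs of the miR-200 family (43.1 ± 3.2), and in the window shared by TARS3 and TM2D3 (42.0 ± 4.5). The largest gain over all tiles was 66.2 points, at a tile outside that rule. At MIR200BHG the naive cells were also above conventional ones, at 41.9% ± 6.5 in HES-1 and 45.6% ± 1.1 in HES-2, against 11.2% ± 1.2 and 17.3% ± 6.2. At LEFTY1, UTF1 and IFITM1 no naive group exceeded 3.4%.

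The tiles that gained had a mean level of 29.4% in HES-1 and 39.3% in HES-2 conventional cells, and of 56.9 and 66.0% in LN cells. In the naive cells the same tiles stood at 17.5 and 17.9%. They formed 674 regions and the median gain was 25.5 points. Each line alone gave a similar number, 922 higher and 31 lower tiles in HES-1 and 873 higher and 30 lower in HES-2; 352 tiles were called higher in each, where independent calls would share 12.6, and 92.1% of the HES-1 gains and 98.6% of the HES-2 gains had the same sign in the other line. The losses were shared less: 2 tiles were called lower in each line, and 93.5% of the HES-1 losses but 56.7% of the HES-2 losses had the same sign in the other line. Chromosome X held 3 of the called tiles among its 1718, against 874 among 61811 on autosomes (odds ratio 0.122, Fisher's exact p = 1.6e-07). That test takes tiles as independent, which neighbouring tiles are not, and its p-value does not measure the spread between libraries.

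Of the 5 genes that were lower in LN cells, 3 are zinc finger genes of chromosome 19 and another is the antisense gene ZNF667-AS1 beside ZNF667. ZNF667 fell from 69.3% ± 14.7 to 8.5% ± 4.8 in HES-1, whereas in HES-2 it was at 80.7% ± 1.5 and 77.3% ± 3.6, a difference between the lines of -57.5 points (SE 7.7, adjusted p = 0.0063). ZNF667-AS1 differed by -23.2 ± 4.4 SE over both lines, with 57.9 and 14.8% in conventional and LN cells of HES-1 but 79.5 and 76.3% in HES-2. A tile at ZNF790-AS1 (-20.8 ± 2.8) had 65.8 and 30% in HES-1 and 92 and 86.3% in HES-2. Single tiles at ZNF433 (-21.5 ± 3.4) and ZNF471 (-21.2 ± 3.4) were lower, ZNF433 with 11.9 and 1.8% in HES-1 and 78.5 and 45.6% in HES-2. Of 13422 genes, 65 were higher and 5 lower, and 4 of those 5 belong to the zinc finger list of 386 (camera adjusted p = 1.6e-04, and 0.0010 with an estimated correlation, below other genes). The list's median difference was 0, and at an unadjusted p under 0.05 46 of its genes were higher and 41 lower. The fifth gene, PCDHA11, fell from 79.9% ± 14.2 to 55.7% ± 13.5 in HES-1 and from 83.7% ± 4.2 to 52.2% ± 7.8 in HES-2 and was the only called gene of the protocadherin list (1 of 22; camera adjusted p = 0.0046, and 0.027 with an estimated correlation).

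HOX genes shifted upward as a group by small amounts. None of the 31 was called by limma, but 21 were higher and none lower at an unadjusted p under 0.05, the median difference was 1.44 points and the largest 19.5 (camera adjusted p = 3.2e-10, and 0.0046 with an estimated correlation). Some of these genes share tiles, as HOXD3 and HOXD4 do, so the 21 are not independent. The test was not matched on starting level. LEFTY1 was the only called member of the germ layer list (1 of 36; camera adjusted p = 0.34) and MEI1, a gene of meiotic recombination, of the germline list (1 of 22, 20.8 ± 3.6 SE; camera adjusted p = 0.81). No member was called in the lists for naive pluripotency (2 of 11 at an unadjusted p under 0.05), the post-implantation epiblast (1 of 14), core pluripotency (4 of 6), imprinted genes (4 of 30), trophoblast (3 of 8), the methylation machinery (1 of 9), recurrently aberrant genes (1 of 14), fibroblast (2 of 8) and neural genes (1 of 12), with camera adjusted p-values from 0.20 to 0.95. The germline list had a negative median (-0.24) and a positive mean (2.09), and the imprinted list a positive median (0.02) and a negative mean (-0.54). ZFP42 differed by -2.2 ± 2.9 SE (adjusted p = 0.78) and TFCP2L1 by 0.0 ± 0.1 (adjusted p = 0.88).

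The number of tiles depended on the size required: with at least 10 points 2440 tiles were called, and with no minimum 4949. Several small calls did not survive the loss of a library or a centring of the libraries: the protocadherin list turned (adjusted p = 0.69) and the zinc finger list was lost (0.31) when libraries were centred, the protocadherin list was lost without HES-1 LN replicate 2 (0.073), and ZNF790-AS1, ZNF471 and MEI1 fell below 20 points when single libraries were left out.

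**Figure D3:**
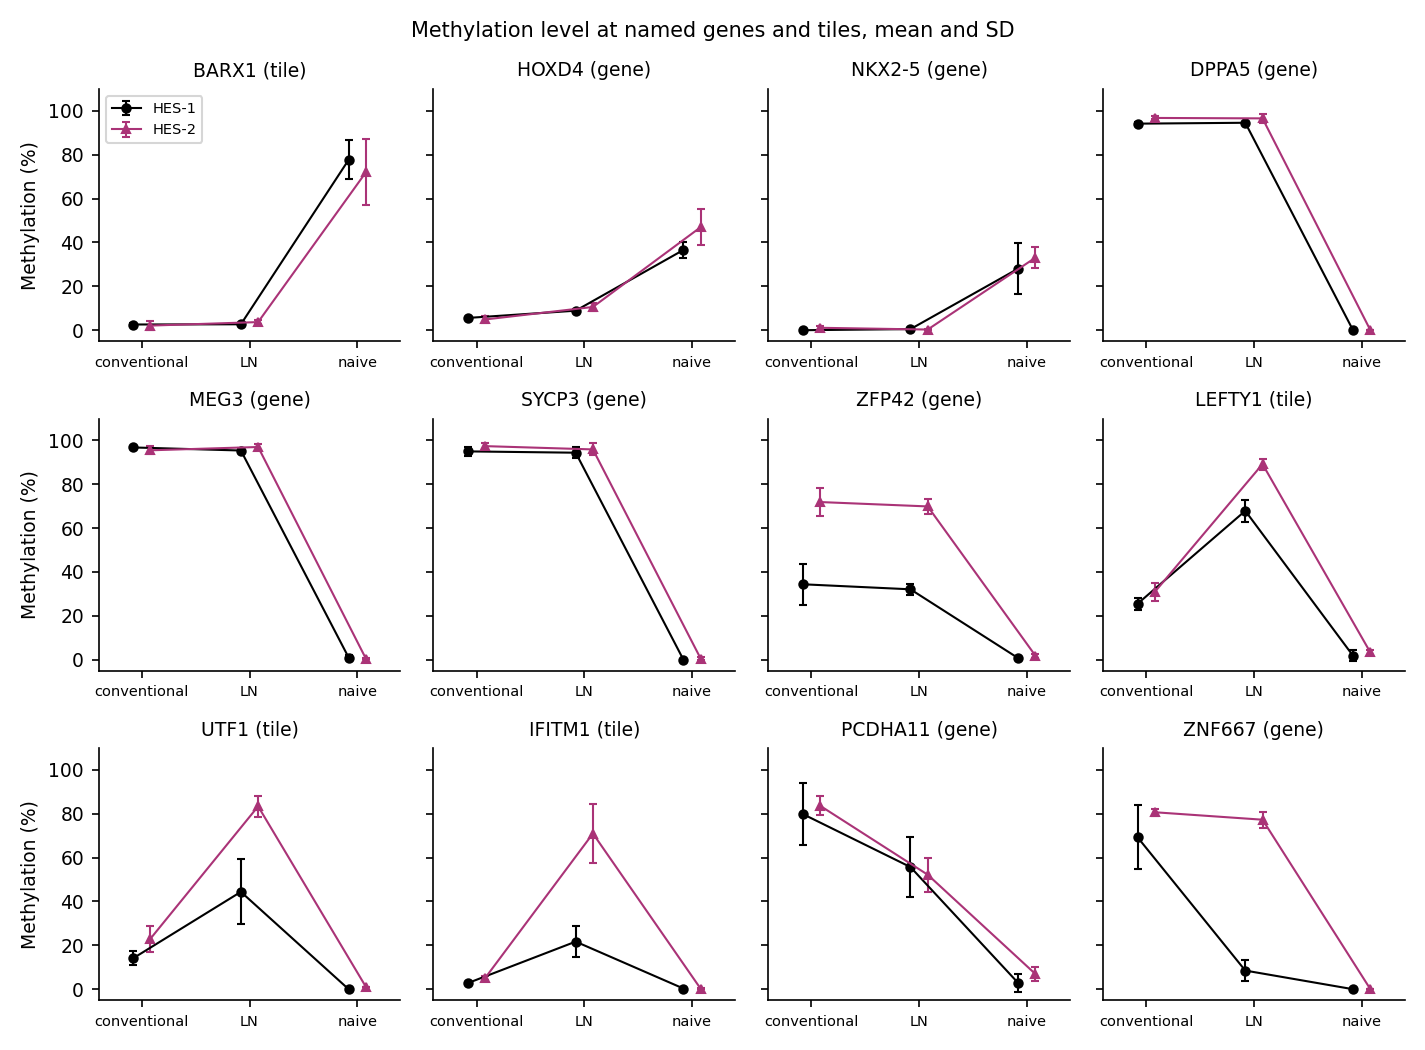
Methylation level (%) of 12 named tiles or genes (mean over the tiles at a gene's ends) in conventional, LN and naive cells, as the mean and SD of each group's libraries, circles for HES-1 and triangles for HES-2. BARX1, HOXD4 and NKX2-5 are high in naive cells alone, LEFTY1, UTF1 and IFITM1 in LN cells, and DPPA5, MEG3 and SYCP3 are near 0 in naive cells.

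LN and naive cells were compared directly to place the laminin culture between the other states. LN cells kept the methylation that naive cells lacked: 24185 tiles were higher and 500 lower in LN cells, and at gene level 2117 genes were higher and 42 lower. Large differences lay at TPTE (97.5 ± 0.7 SE), RNU6ATAC, a small nuclear RNA gene (97.4 ± 2.1), the sulfotransferase gene SULT1A1 (97.1 ± 1.0), MEG3 (96.8 ± 1.6), ETFRF1P1 (96.7 ± 1.0), RPS15P9 (96.6 ± 1.1) and NAPSA (96.6 ± 1.0). LEFTY1 differed by 76.0 points (SE 2.2). Lower in LN cells were BARX1 (-71.6 ± 3.8), LINC01956 (-61.8 ± 1.7), MIR4740 (-58.4 ± 2.0), LINC00682 (-57.9 ± 1.6), LINC03010 (-57.8 ± 2.7), IRX6 (-54.7 ± 3.3), the shared HOXD3 and HOXD4 tile (-53.4 ± 3.1) and CBLN1, a synaptic organiser gene (-51.4 ± 3.0).

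By list, LN cells were higher at 16 of 22 germline genes (camera adjusted p = 1.1e-07, and 0.0029 with an estimated correlation) and 15 of 22 protocadherins (1.7e-06 and 0.0029). Germ layer regulators were higher at 1 and lower at 2 of 36 and stood below other genes (1.7e-06 and 0.0029), as did the post-implantation genes with none of 14 called and 8 at an unadjusted p under 0.05 (7.7e-05 and 0.0039). These list tests were not matched on level either. Germ layer and post-implantation genes were low in all 3 cultures, so their place below other genes can follow from that alone. Recurrently aberrant genes, higher at 6 of 14, and neural genes, higher at 1 of 12, passed camera (adjusted p = 0.037 and 0.022) but each had an adjusted p = 0.066 with an estimated correlation. HOX genes were higher at 1 and lower at 3 of 31 (0.54), imprinted genes higher at 9 of 30 (0.31), naive pluripotency genes at 3 of 11 (0.31), zinc finger genes higher at 72 and lower at 2 of 386 (0.31), and methylation machinery genes higher at 2 of 9 (0.52). Fibroblast genes were higher at 2 of 8 (0.31), and no core pluripotency gene of 6 (0.82; 3 at an unadjusted p under 0.05) and no trophoblast gene of 8 (0.20; 5 at an unadjusted p under 0.05) was called. The HOX list had a median of 1.1 and a mean of -0.77 points, the trophoblast list -0.13 and 3.63, and the fibroblast list -0.1 and 9.01. Without HES-1 LN replicate 1, HES-2 naive replicate 0 or HES-2 naive replicate 1 the recurrently aberrant list was lost (adjusted p = 0.052, 0.060 and 0.053), as was the neural list without HES-1 naive replicate 0 (0.067). With centred libraries the post-implantation, germ layer, recurrently aberrant and neural lists were lost (0.21, 0.21, 0.065 and 0.45).

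Whether LN and naive cells departed from conventional cells at the same places was examined on the tiles called in both comparisons. Of the 861 tiles higher in LN cells, 373 were lower in naive cells, where independent lists would share 313, and 38 were higher, where 8.54 would be shared. All 17 tiles that were lower in LN cells were also lower in naive cells (6.19 from independent lists). These 17 tiles had mean levels of 56.2% in HES-1 and 73% in HES-2 conventional cells, so they were able to fall. Most tiles able to fall did so in naive cells. The 6.19, taken over all tiles, therefore understates the overlap that the starting level alone would give, and shared places of loss cannot be inferred from it. The expected counts for the tiles higher in LN cells were not matched on starting level either. The 2 comparisons share their conventional libraries, and the covariance of the differences over tiles was 12.2 against 1.64 in 100 simulations of unchanged groups, an excess of 10.5; with the conventional libraries divided between the comparisons it was 10.9 on average over 9 divisions (8.39 to 13.6). The correlation across tiles, which are not independent replicates, was 0.0949 (0.448 in the simulations and 0.0821 with divided libraries). The same sign was found at 53.4% of tiles (65.5% in the simulations and 46.5% with divided libraries). No tile was called in both comparisons in the 10 simulations in which calls were made. The simulated groups held no change, and unchanged tiles were hardly ever called (0 and 1 of 63504 when the fit was tested). This absence could hardly come out otherwise and says nothing about the shared calls. The simulations show only what shared libraries give without any change. Both observed changes varied with starting level, on which the covariance was not matched. The excess of 10.5 cannot tell shared places of change from a shared dependence on starting level.

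The lines were compared to set a yardstick for the culture differences. HES-1 was less methylated than HES-2, above all on chromosome X: averaged over conditions, 1330 tiles were lower and 76 higher in HES-1, and 26.4% of the chromosome X tiles were called against 1.53% on autosomes (odds ratio 23.13). In conventional cells the mean of chromosome X was 38.4% ± 0.03 in HES-1 (n = 3) and 53.4% ± 1.46 in HES-2 (n = 3), and in LN cells 37.9% ± 0.99 (n = 3) and 53.2% ± 0.58 (n = 3). Naive cells of the lines were alike at 15.18% ± 0.39 (n = 2) and 14.96% ± 0.06 (n = 2). The level of chromosome X minus that of autosomes differed between HES-1 and HES-2 by -13.03 points in conventional, -13.18 in LN and 0.07 in naive cells (mean over conditions -8.71, exact permutation p = 0.005).

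At gene level 165 autosomal and 110 chromosome X genes were lower in HES-1, and 13 autosomal and 1 chromosome X gene higher. The following examples were chosen after their values were seen. Zinc finger genes of chromosome 19 differed in both directions. In conventional cells of HES-1 and HES-2, ZNF90 had 0.2 and 91.4%, ZNF682 0.4 and 93.8%, and ZNF486 18.7 and 93.1%, whereas ZNF440 had 77.2 and 11.8% and ZNF441 92.2 and 33.4%. LYNX1, whose product modulates acetylcholine receptors, had 0.1 and 93.6%, and the cytochrome P450 gene CYP4F22 3.0 and 96.0%. Also higher in HES-1, MCRIP2 on chromosome 16 had 81.3 and 0.2%, and MGMT, a DNA repair gene, 86.4 and 51.5%. On chromosome X, ARMCX1 had 4.5 and 50.6%, and PRPS2, a gene of nucleotide synthesis, 0.5 and 51.5%.

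The change with culture also differed between the lines. For naive minus conventional the interaction of line and culture was called at 1890 tiles, 1729 of them with the smaller loss or larger gain in HES-1, and 26.7% of chromosome X tiles were among them against 2.29% of autosomal tiles (odds ratio 15.49). The mean of chromosome X minus autosomes fell by 5.64 points from conventional to naive HES-1 cells and fell by 18.74 in HES-2 (difference 13.1), and for the mean over all tiles the lines differed by 2.4 points. In a permutation test of the line labels, after the line difference averaged over both conditions was removed, each had p = 0.017, the smallest the design allows; this form was chosen after the data were seen. With the line difference kept, the permutation p was 0.017 for chromosome X and 0.05 for the mean over all tiles. ZFP42 had the larger fall in HES-2, by 36.5 points (SE 6.5, adjusted p = 0.0053). In conventional cells HES-1 minus HES-2 was -13.03 points for chromosome X minus autosomes and -2.24 for the mean over all tiles. In naive cells these were 0.07 and 0.16. ZFP42 was at 34.4% in HES-1 and 71.9% in HES-2 conventional cells, and at 0.7 and 1.8% in naive cells. For these measures the interaction largely restates the line difference in conventional cells.

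For LN minus conventional the interaction was called at 97 tiles, 71 of them positive and 1 on chromosome X. The change of chromosome X relative to autosomes was -1.49 points in HES-1 and -1.35 in HES-2 (mean -1.42, exact permutation p = 0.01; difference between the lines -0.14, permutation p = 0.91 with the line difference removed), and with medians over tiles in place of means it was -1.05 (exact permutation p = 0.18). The count of 97 was the least stable of those reported, and fell to 3 on a logit scale.

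**Figure D4:**
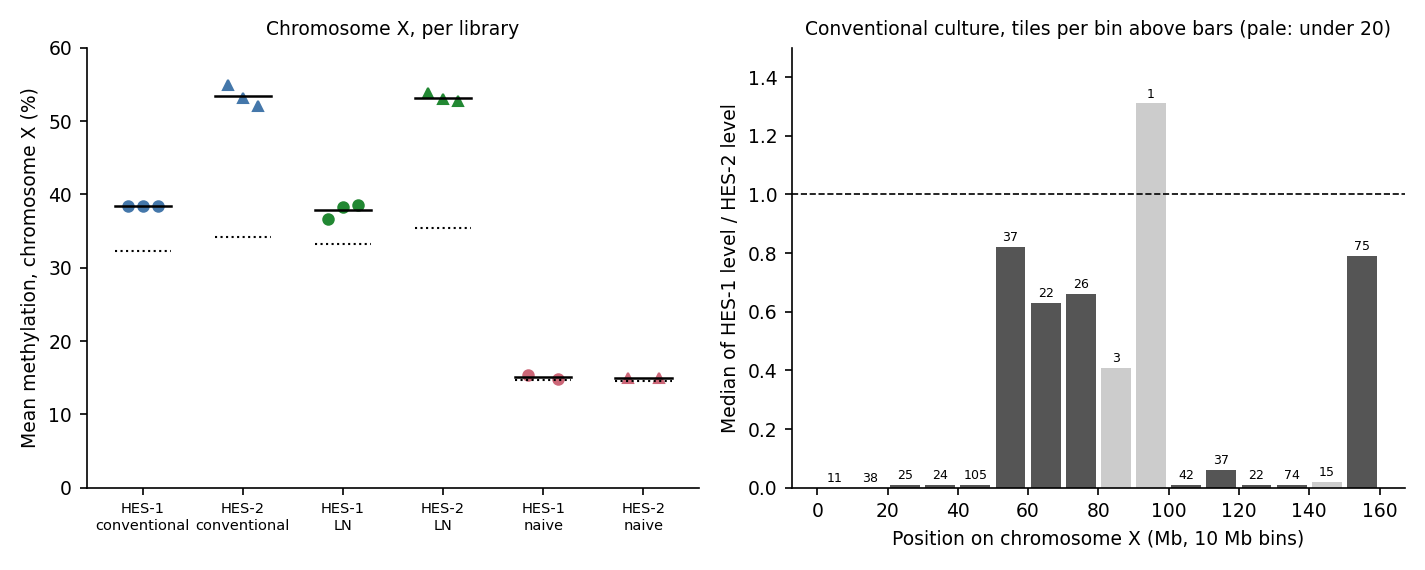
Left, the mean methylation level (%) of chromosome X in each library, by line and culture condition, with solid lines at group means and dotted lines at the autosomal group means; right, the median ratio of the HES-1 to the HES-2 level in conventional cells in bins of 10 Mb, over tiles at 30 to 60% in HES-2 and below 5% in naive cells, with the number of tiles above each bar and bins under 20 tiles in pale grey. HES-1 lies below HES-2 in conventional and LN cells, and the ratio is near 0 in most bins but 0.82 at 50 Mb, 0.63 at 60 Mb, 0.66 at 70 Mb and 0.79 at 150 Mb.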

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

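The uniform-difference test of chromosome X and the tests with the line difference removed were chosen after results they bear on were seen. Chance was examined by regrouping libraries: of 100 splits within line, only the real split gave as many called tiles for LN against conventional cells (1 of 100; 878 tiles, 45 in the highest other split), for naive against conventional cells (1 of 100; 23823 and 1921) and for LN against naive cells (1 of 100; 24685 and 11017). The same held for HES-1 against HES-2 over splits within condition (1 of 100, with 1406 and 12 tiles). This argues against a chance division of these libraries for these 4 counts. For the comparisons with naive cells only 100 splits exist, so no smaller share was possible. Chance differences between cultures are not tested, because the labels do not say whether replicates were separate cultures. Within HES-1 and within HES-2, LN against conventional cells had 953 and 903 called tiles and at most 1 and 3 in another split (1 of 10 splits each, the real one), and 10 splits are too few for a share under 0.05.

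Several results stand out because the test of line by culture found changes that differed between the lines. The loss from conventional to naive cells differed between HES-1 and HES-2 at 1890 tiles, the loss of mean methylation differed by 2.4 points and that of chromosome X relative to autosomes by 13.1 points. At ZFP42 the lines differed by 36.5 points in this contrast. The naive levels of the lines were alike for both means and at ZFP42, so there the interaction largely restates the line difference in conventional cells. For LN minus conventional the lines differed at 97 tiles, at IFITM1 by -46.9 points and at ZNF667 by -57.5. Line labels split within the conventional and LN libraries turn the difference between the lines into an apparent interaction: in this first form of the test 5 of 100 splits gave as many as 97 tiles, up to 4136, which does not exclude chance. After that difference was removed at each tile, a form chosen after the first was seen, only the real split (1 of 100) gave as many, with at most 1 tile in another. The second form alone argues against a chance division of the libraries for this count, and the count depends on the scale.

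Chromosome X was less methylated in HES-1 than in HES-2 in conventional and LN cells. A difference that touches all chromosomes alike is argued against by the size of the gap: it was -14.92 points on chromosome X in conventional and -15.36 in LN cells, at least 4.2 times that of the most different autosome, chromosome 19 (-3.47 and -3.66). Loss of a methylated copy of chromosome X in a share of the HES-1 cells would lower all of its intermediate tiles by the same factor. Over 557 tiles at 30 to 60% in HES-2 and below 5% in naive cells, the ratio of HES-1 to HES-2 instead had an SD 3.74 times that of replicate noise: 69.8% of the tiles had a ratio below 0.2 and 16.7% a ratio above 0.8. A difference between the lines that is confined to regions of chromosome X may account for the pattern; this is a hypothesis from the same data, and copy number was not analysed here.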

How the results depend on the processing

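The labels give the groups the same replicate numbers, but the numbers do not pair the samples: none of 14 same-line pairs of libraries had deviations correlated above 0.1 (-0.024 to 0.038 over 27868 tiles), and 6 of 16 libraries were best matched by their own number. With the replicate block, naive against conventional, LN against conventional and LN against naive had 23857, 868 and 24739 called tiles. The neural list, adjusted p = 0.058 for naive against conventional cells, had 0.049 with it. It moved the 97 tiles of the LN interaction to 47, and left global differences of -19.11 points (naive minus conventional) and 20.08 (LN minus naive) with an exact permutation p of 0.125, the smallest possible. The logit scale left 3 of the 97 tiles. Leaving out a library gave 56 (without HES-1 naive replicate 0 or 1) to 112 tiles (without HES-1 LN replicate 2), and 64 without HES-1 or HES-2 conventional replicate 1. A minimum of 10 points gave 2440 tiles for LN against conventional cells, 1653 in HES-1, 1751 in HES-2, 2849 for the naive interaction and 3170 between the lines; no minimum gave 4949 for LN against conventional cells, a looser rule by construction. Centring left 3 of 7, 1 of 3 and 2 of 6 lists for naive against conventional, LN against conventional and LN against naive cells, and turned the protocadherin list of LN cells (adjusted p = 0.6859). Medians took the LN change of chromosome X to -1.05 points, and limits of 10 and 90% turned the highest class of LN cells to -0.6. Apart from the construction named, the cause was not tested. Of the remaining recomputed values that answer a comparison, 469 kept their direction and side of the threshold, or as counts stayed within 1.5 times. Of those for single lists and genes, 2551 did so, 26 lost and 6 gained a call; leaving out each library in turn gave 23724 to 23875 tiles for naive against conventional cells and 831 to 938 for LN against conventional cells. Of the values recomputed for named genes, 1778 kept their call and 8 fell below 20 points: ZNF790-AS1 (-18.2 to -20 without HES-1 LN replicate 0, HES-1 conventional replicate 1 or HES-2 LN replicate 1), ZNF471 (-19.9 and -18.9 without HES-1 conventional replicate 2 or HES-2 LN replicate 2) and MEI1 (17.1 to 19.9 without HES-1 LN replicate 1, HES-2 LN replicate 0 or HES-2 conventional replicate 1). Coverage minimums and tiles with missing values could not be tried, since the table has neither coverage nor missing values, and unknown depth limits what can be said of single tiles.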

Other observations

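The tests of transcription factor families, of bisulfite conversion, of feeder DNA and of the correlation of the lines below were chosen after the results they bear on were seen, and the genes named were chosen after their values were seen. Gains of methylation in naive cells also lay at genes outside the HOX clusters. Counting tiles anywhere in a gene or its end windows, 224 of 13506 protein-coding genes held a tile that was higher in naive cells, and 67 of 250 genes of developmental transcription factor families did, against a mean of 9.8 and a highest count of 24 in 10000 random gene sets matched on the number of tiles (permutation p = 1e-04, the smallest these sets can give). Those families include genes whose gains prompted the test, such as HOXD3, HOXD4, BARX1 and IRX6. No NKX gene was among the 67, although NKX2-5 gained methylation. Some of the 67 share a gained tile, as HOXC4, HOXC5 and HOXC6 do. Without the HOX, BARX, IRX, NKX and TBX families, 42 of 193 genes held such a tile, against a mean of 6.8 and a highest count of 17 (permutation p = 1e-04, again the smallest). Their largest gains lay at 42 distinct tiles. Random sets were not matched on the starting level, which limits how far a tile can rise. OSR2, a zinc finger gene of palate and limb development, went from 4.8 to 76.8% in HES-1 and from 3.1 to 71.8% in HES-2 at chromosome 8, 98949501 to 98949600. GATA4, a regulator of heart and endoderm, went from 3.9 to 77.5% and from 1.3 to 65.6%, SIM1 from 0.9 to 72.9% and from 2.6 to 67.1%, and TBXT, the mesoderm gene also called Brachyury, from 5.6 to 47.8% and from 8.6 to 48.9%. In LN cells these 4 tiles were between 0.7 and 6.3%, but other tiles were higher in LN than in conventional cells: at HOXB1 23.4 against 5.7% in HES-1 and 28 against 6.8% in HES-2, and at LHX6 27 against 13.1% and 56.3 against 35.5%. The tile with the largest naive gain was at least 10 points higher in LN cells of a line at 10 of the 67 genes. Many genes of these families are Polycomb targets in pluripotent cells, and a loss of protection from methylation at such sites in naive culture is a hypothesis that these data do not test further.

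Tiles in the middle of the range gained methylation in LN cells, while those at either extreme hardly moved. With tiles sorted by the conventional level of the other line, so that the sorting does not share libraries with the change, HES-1 tiles at 40 to 60% rose by 9.49 points on average and HES-2 tiles by 9.88. Tiles at 0 to 5% rose by 0.37 and 0.41 points, and those at 90 to 100% changed by -0.9 and -0.17. Incomplete bisulfite conversion in the LN libraries would raise unmethylated tiles most, but at the 33044 tiles below 5% in the conventional and naive groups of both lines the median change was 0.03 points in the line with the larger change and 0 in the other. Fully methylated other cells would have to make up 90.9% of an LN culture for the gain that needs the most of them, and unmethylated DNA of mouse feeder cells would have to supply 92.8% of the conventional reads in the line that needs more and 81.6% in the other. Libraries of LN and conventional cells correlated across tiles at 0.987 to 0.992 in HES-1 and 0.988 to 0.992 in HES-2, so other cells at such a share would need nearly the same profile. Feeder reads could lower only tiles where mouse sequence aligns, which was not analysed here, and both sources and an effect of the laminin culture stay open.

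The difference between the lines was smaller in naive than in other cultures, although single libraries did not correlate better. HES-1 with HES-2 libraries correlated across tiles at 0.96 on average in naive cells, 0.978 in conventional and 0.981 in LN cells, while the naive replicates of a line correlated at 0.961 and 0.971. Noise in the naive libraries could hide a line difference, so the covariance over tiles between the line difference in replicate 0 and that in replicate 1 was used, which noise does not enter. It was 8.9% of that in conventional cells (6.06 against 67.79, with 56.74 in LN cells), and naive levels span a smaller range. With noise removed in the same way, the correlation of the lines, which sets the line difference against the spread of levels in each culture, was 0.995 in naive, 0.982 in conventional and 0.985 in LN cells. Whether the smaller range alone accounts for the difference stays open. A removal of line-specific methylation in naive culture may explain it, as a hypothesis found and examined on the same data.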
